A study of Homo sapiens with 6 samples.

How the data were processed

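H1975 cells with inducible hairpins were crosslinked for 10 min in 1% formaldehyde, and chromatin was sheared to between 100 and 1000 bp, per the labels' protocols. Libraries were sequenced as paired-end reads of 75 bp. Bowtie2, MACS version 1.4.2 and the hg19 build are named per the submitters' processing notes. The table names refer to MAnorm, which rescales 2 libraries on their common peaks, and the header holds a HOMER annotation command; versions of both are not given in the sources used here. The 6 samples were grouped by hairpin and by H4ac or input from their titles, 1 library per group.

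Each deposited table lists the regions of 1 knockdown library against the control, as common or unique regions from the knockdown or the control peak list. A region's identifier, split over several columns per the file headers, gives the read counts of both libraries as deposited whole numbers, not normalised. It also gives M, the log2 ratio of knockdown over control, and A, the mean log2 signal, both rescaled by the authors. The peak score is the −log10 of the deposited p-value of the 2 libraries, not adjusted for the number of regions. The column order was taken from the comparison named in the header; at all 36034 control peaks the control read counts were equal in both tables, and the knockdown counts were equal at 134. The score column holds 0 where the identifier gives an infinite or missing p, so p was read from the identifier. With shTIP60-B, 11 regions had an infinite p, counted as past the p threshold, and 11 had none, counted as not past it. With shTIP60-C these were 3 and 1. Counts, M and p of named regions are the authors' deposited values; everything else was computed here.

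Distances to the nearest start site and gene names came from the deposited HOMER annotation. A promoter region lies within 1 kb of a start site, and a gene was represented by its promoter region with the highest mean signal. A region or promoter passed with a fold of at least 2 and a deposited p of at most 1e-05. Named genes are, per hairpin, the 10 lowest and 10 highest that passed, up to 10 per direction that passed with both, KAT5, up to 4 members of each list called shifted, and 3 distal regions per direction. Genes without a symbol (2 were passed over) and small or antisense RNAs were not named. Some genes that the rule picks are not reported here. DDIT4, named with both hairpins, is also given for shTIP60-B.

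Counting intervals of M are exact Clopper-Pearson intervals of the 2 read counts at 95% confidence, shifted by the authors' rescaling of that region. A count of 0 was set to a floor of 3 counts per library after scaling by the table totals. Median reads per region were 49 for shTIP60-B and 57 for the control in the shTIP60-B table, and 111 and 57 in the shTIP60-C table, so ratios with shTIP60-C are the more precise. The rescaling differed with signal in the shTIP60-B table: its median was -0.01 (log2) in regions of low A and -0.31 in those of high A, against 0.97 and 0.91 in the shTIP60-C table.

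The 31 gene lists hold 771 entries. A name was matched to the deposited symbols, or to their deposited aliases where it is no longer a symbol in the RefSeq gene table of GRCh38.p14, used for names alone; 677 were named in the annotation, 4 of them by alias, and 574 had a promoter region in both tables. This rule for aliases was made stricter after values of list members had been seen, because the first one had put wrong genes into lists; the same 4 lists were called with both rules. A list's median M was ranked among 10000 random lists of the same size drawn from 20 signal bins, and called shifted below the percentile 1 or above 99 with both hairpins. By chance 0.62 of the lists would pass with 1 hairpin. Regions of the tables were matched by at least 50% reciprocal overlap. The value that the shared control gives by itself was simulated with 100 Poisson draws. Chromosome medians carry intervals from 1000 bootstrap draws of regions. Ratios were also centred on the median of their 10 Mb window, where it held at least 50 regions.

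A form of the rule with ratios scaled by totals and an exact binomial p was tested on simulated data made from the real read counts. The deposited M and p were not tested, so the shares below do not give the recovery by the deposited p. Only regions above a minimum read total were changed. With shTIP60-B this form recovered 96.0% of 50 regions lowered to 0.25 and 70.0% of 50 lowered to 0.33. With shTIP60-C these were 92.0% and 82.0%. All 50 regions raised 3-fold and all 50 raised 4-fold were recovered with each hairpin. This form called 0 of 39016 and 0 of 39224 unchanged regions, with 39216 and 39424 regions run. These simulations hold counting error and no difference between cultures.

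Before the data were examined, other fold and p thresholds, 2 other scalings, a filter on low signal, an exact binomial p, a 3 kb promoter and other ways to match regions were fixed as alternatives. The step, 0.5 Mb window and X centromere summaries, window centring (also with histone regions left out of the window medians), leaving out knockdown copies of shared regions and leaving out shifted chromosomes were added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.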

Results

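Acetylated histone H4 (H4ac), a mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing in H1975, an established lung adenocarcinoma line that carries mutant EGFR. The cells held doxycycline-inducible hairpins against TIP60 (gene KAT5), a lysine acetyltransferase whose substrates include histone H4. There were 6 libraries: 1 H4ac and 1 input library each for a control hairpin (shControl) and for the hairpins shTIP60-B and shTIP60-C, all after 2 days of 0.5 ug/ml doxycycline. The design has no replicates, so no difference below has a replicate check, and each p compares 2 libraries, not 2 conditions. The 2 deposited tables set shTIP60-B and shTIP60-C against the same control library over H4ac regions on the hg19 build. The shTIP60-B table listed 63299 regions with 5508475 shTIP60-B reads and 6706229 control reads in them. The shTIP60-C table listed 66546 regions with 13429202 shTIP60-C reads and 7043106 control reads. Input reads were not used here. The authors' rescaling on common peaks, like scaling by table totals, takes out any H4ac change shared by all regions. Falls and rises below are thus relative to other regions, and a loss over the whole genome was not measured. Ratios (M, log2 of knockdown over control) and p-values of single regions are those of the authors' deposited table. Intervals in parentheses after M of single regions or shares of reads are 95% counting intervals, which cover counting error only.

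The targeted gene comes first. The KAT5 promoter (chromosome 11, 65478158 to 65480249) had M = 0.20 (-0.01 to 0.41) with shTIP60-B, from 350 knockdown and 402 control reads. With shTIP60-C it had M = 0.23 (0.06 to 0.41), from 882 and 405 reads. Neither passed the rule used throughout, a fold of at least 2 with a deposited p of at most 1e-05. A hairpin acts on the transcript, so promoter acetylation does not check the knockdown.

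The comparison of shTIP60-B with shControl asked where H4ac differed after the first hairpin. Acetylation fell at the promoters of 400 genes and rose at those of 148, of 11541 genes with a promoter region. Among the genes that fell were IRF9, MX2, IRF7 and IFI44L of the interferon response, the Iroquois factor gene IRX5 and MVD, which encodes an enzyme of cholesterol synthesis. Genes that rose included CDCP1, a transmembrane substrate of SRC kinases, the amino acid transporter gene SLC43A1 and DDIT4, an inhibitor of mTORC1 signalling. Whole chromosomes also differed with this hairpin: the median M was -0.69 on chromosome 20 and -0.49 on chromosome 16.

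The lowest promoter ratios with shTIP60-B rested on few reads. IRX5 (chromosome 16, 54964688 to 54965501, promoter) had 2 against 35 reads, M = -3.81 (-7.45 to -2.39). The IRX5 promoter region used with shTIP60-C (54963675 to 54964615) does not overlap it and had M = -0.36. PKD1, the polycystin-1 gene, had M = -3.54 (-7.19 to -2.10) and C18orf32 had M = -3.49 (-7.14 to -2.04), each from 2 knockdown reads. NBPF12 had M = -3.42 (-5.64 to -2.26) and C5orf38 M = -2.87 (-4.79 to -1.75). FAM129A, MVD and POP3 had M = -2.72, -2.65 and -2.59. With shTIP60-C, PKD1, C18orf32 and C5orf38 had M = -1.31, -1.03 and -0.83. NBPF12, FAM129A and POP3 had M = -0.31, -0.44 and -0.28 there, and MVD had M = 0.42. None of these genes passed with shTIP60-C. IRX5, PKD1 and MVD lie on chromosome 16, which had a low median as a whole.

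At the other end, PPIP5K1, an inositol pyrophosphate kinase gene (chromosome 15, 43882514 to 43883021, promoter), had 18 knockdown and 0 control reads, at least 7.30-fold higher against a floor of 3 counts in the control library, scaled by the table totals. The floor leaves out the counting error of the 18 reads, and the counting interval of M reached down to 2.16. TMOD2, a tropomodulin gene, had 27 against 2 reads, M = 3.29 (1.83 to 6.94). The trafficking adaptor gene TRAK1 and the pyridoxal phosphatase gene PDXP each had 26 against 2 reads, M = 3.24 (1.77 to 6.89). KIAA1161 and FLVCR2 had M = 3.14 (1.83 to 5.86) and 3.05 (1.56 to 6.70). UBE3D (chromosome 6, 83775001 to 83776098) had 59 against 9 reads, M = 2.76 (1.86 to 4.08), with a deposited p of 3.8e-12. ENTPD2, an ectonucleotidase gene, and CDCP1 had M = 2.69 and 2.49, and SLC43A1 was 5.67-fold higher. In the shTIP60-C library TRAK1, UBE3D, ENTPD2 and CDCP1 had M = 1.81, 2.12, 1.87 and 1.84, none past the rule there. PPIP5K1, TMOD2, PDXP, KIAA1161, FLVCR2 and SLC43A1 had no promoter region in the shTIP60-C table.

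Over all regions, 1968 fell (3.11% of 63299, 95% Wilson interval 2.98 to 3.25) and 1294 rose (2.04%, 1.94 to 2.16) with shTIP60-B. These Wilson intervals treat listed regions as independent. Shared regions are listed as copies and calls gather on some chromosomes, so the intervals understate the uncertainty. Promoter regions, within 1 kb of a start site, held 697 that fell (3.08%) and 231 that rose (1.02%). Distal regions held 1271 (3.13%) and 1063 (2.61%). The median M was -0.11 over 22616 promoter regions (quartiles -0.50 and 0.25) and -0.06 over 40667 distal regions (-0.61 and 0.42). The sign of the distal median turned with scaling by the table totals, to 0.05. Regions shared by both peak lists appear in the table as a knockdown and a control copy, and without the knockdown copies 1434 regions fell and 722 rose. With an exact binomial p in place of the deposited one, 1490 fell and 1525 rose, so the excess of regions that fell rests on the deposited p.

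Whole chromosomes or long stretches of them differed with shTIP60-B. The median M of chromosome 20 was -0.69 (bootstrap interval -0.72 to -0.66) with -0.70 at promoter and -0.68 at distal regions. Chromosome 16 had -0.49 (-0.53 to -0.46), and chromosomes 10, 3 and 9 had 0.25, 0.24 and 0.20. Steps lay inside chromosomes: from -0.15 to -0.56 near 130 Mb on chromosome 1, from 0.02 to -0.39 near 70 Mb on chromosome 7, and from -0.13 to 0.35 near 40 Mb on chromosome 10. In the shTIP60-C library the medians of chromosomes 16 and 20 were -0.03 and 0.01, and all 23 chromosome medians lay between -0.10 and 0.09. Outside the 9 chromosomes with a shTIP60-B median of at least 0.2 in either direction, 719 regions fell and 628 rose.

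**Figure D1:**
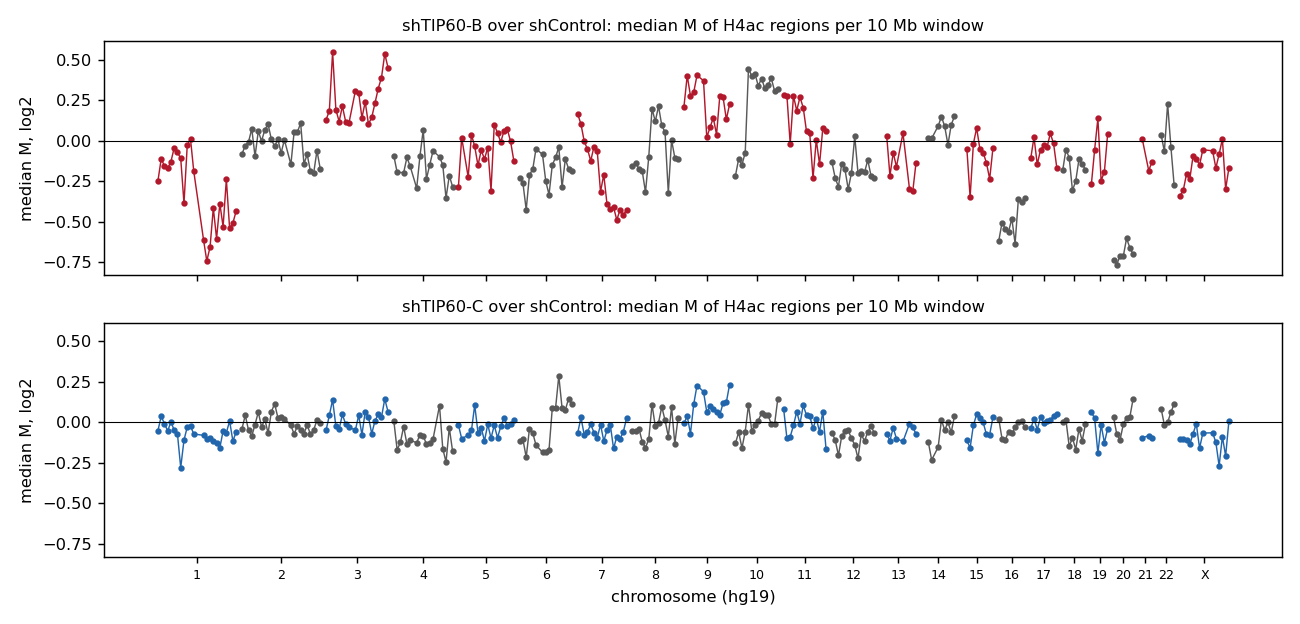
Median M (log2 of knockdown over control H4ac reads, vertical axis) of the regions in each 10 Mb window with at least 50 regions, along chromosomes 1 to 22 and X (hg19, horizontal axis); each point is a window and alternating colours separate chromosomes. With shTIP60-B chromosomes 16 and 20 lie low as a whole and chromosomes 1, 7 and 10 change level midway, while shTIP60-C windows stay between -0.28 and 0.28.

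The comparison of shTIP60-C with shControl asked the same of the second hairpin and gave far fewer calls. Acetylation fell at the promoters of 5 genes, LINC01585, ZNF112, RBM42, CHMP4A and GPR146, and rose at those of 16, of 11549 genes with a promoter region. The genes that rose most were PRKAG3, a regulatory subunit of AMP-activated kinase, SMOX, the spermine oxidase gene, and RPS6KA2, a ribosomal S6 kinase gene. Relative to other regions, their promoters had 5.34-fold, 5.00-fold and 4.70-fold more acetylation than the control.

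LINC01585 (chromosome 15, 91203720 to 91204617, first intron) had M = -2.47 (-3.63 to -1.57) from 12 against 35 reads. The zinc finger gene ZNF112 had M = -1.45 (-1.94 to -0.97), RBM42 had M = -1.37 (-1.83 to -0.93), the ESCRT gene CHMP4A had M = -1.21 (-1.64 to -0.79) and the receptor gene GPR146 had M = -1.07 (-1.45 to -0.69). LINC01585 and CHMP4A had M = -1.91 and -1.15 with shTIP60-B, not past the rule, and GPR146 had M = 0.36 there. Centred in 10 Mb windows, GPR146 no longer passed with shTIP60-C. SMOX (chromosome 20, 4128814 to 4129949, promoter) had 86 against 8 reads, M = 2.32 (1.43 to 3.73). NDUFA4L2, a hypoxia-inducible mitochondrial gene, had M = 1.84 (1.09 to 2.90), SNAP47 M = 1.72 (1.06 to 2.58) and PACS1 M = 1.53 (0.93 to 2.31). TTC37, the negative elongation factor gene NELFB and the taurine transporter gene SLC6A6 had M = 1.46, 1.44 and 1.31.

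Over all regions, 34 fell (0.0511% of 66546, 95% Wilson interval 0.0366 to 0.0714) and 145 rose (0.218%, 0.185 to 0.256) with shTIP60-C. Of these, 26 and 122 were distal. The Wilson intervals again treat listed regions as independent, which they are not. The median M was -0.01 over 23390 promoter regions (quartiles -0.23 and 0.21) and -0.03 over 43139 distal regions (-0.35 and 0.27). With an exact binomial p in place of the deposited one, 158 regions fell and 311 rose. Without the knockdown copies of shared regions, 95 rose.

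The comparison of both hairpins asked which promoters moved with each of them. PRKAG3, RPS6KA2, NUPR1, PPTC7 and DDIT4 rose with both hairpins, and RBM42, an RNA-binding protein gene, fell with both. PRKAG3 (chromosome 2, 219696315 to 219697378, promoter) had 48 against 10 reads with shTIP60-B, M = 2.30 (1.41 to 3.56), and M = 2.42 (1.61 to 3.64) with shTIP60-C. NUPR1, which encodes a stress-induced nuclear protein, and DDIT4 are both known stress genes. Interferon response promoters lay lower and ribosomal protein promoters higher with both hairpins.

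RPS6KA2 (chromosome 6, 167039612 to 167040203, intron 2) had M = 2.33 (1.23 to 4.06) and 2.23 (1.34 to 3.65) with shTIP60-B and shTIP60-C. NUPR1 (chromosome 16, 28549798 to 28550874, 5' UTR) was 2.82-fold and 2.72-fold higher, from 66 against 26 and 150 against 28 reads. PPTC7, a mitochondrial phosphatase gene (chromosome 12, 111019887 to 111021241), had M = 1.49 (0.97 to 2.06) and 1.27 (0.81 to 1.82). DDIT4 (chromosome 10, 74031856 to 74033700, promoter) had 206 against 92 reads with shTIP60-B and 333 against 85 with shTIP60-C. Its M was 1.49 (1.14 to 1.87) and 1.04 (0.71 to 1.42). RBM42 (chromosome 19, 36119315 to 36120496, promoter) had M = -1.25 (-1.83 to -0.73) and -1.37 (-1.83 to -0.93). With an exact binomial p RBM42 no longer passed with both hairpins, and with the mean ratio over a gene's promoter regions DDIT4 no longer did. Without the 25% of regions lowest in signal, the calls of PRKAG3 and RPS6KA2 with both hairpins ended.

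Of 11085 genes with a promoter region in both tables, 389 fell with shTIP60-B and 5 with shTIP60-C, so independent lists would share 0.175 and the tables shared 1. For genes that rose, 124 and 13 would share 0.145 and the tables shared 5. No gene passed in opposite directions. In 100 simulated sets of unchanged libraries that share 1 control, no gene passed with both hairpins, but at most 0 genes passed with shTIP60-B and 1 with shTIP60-C in any set, so this 0 is no measure of what the shared control adds to real calls. Part of the excess may come from the shared control, which cannot be split. Over all matched pairs of regions 66.8% had the same sign with both hairpins, against 68.1% in the simulation.

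**Figure D2:**
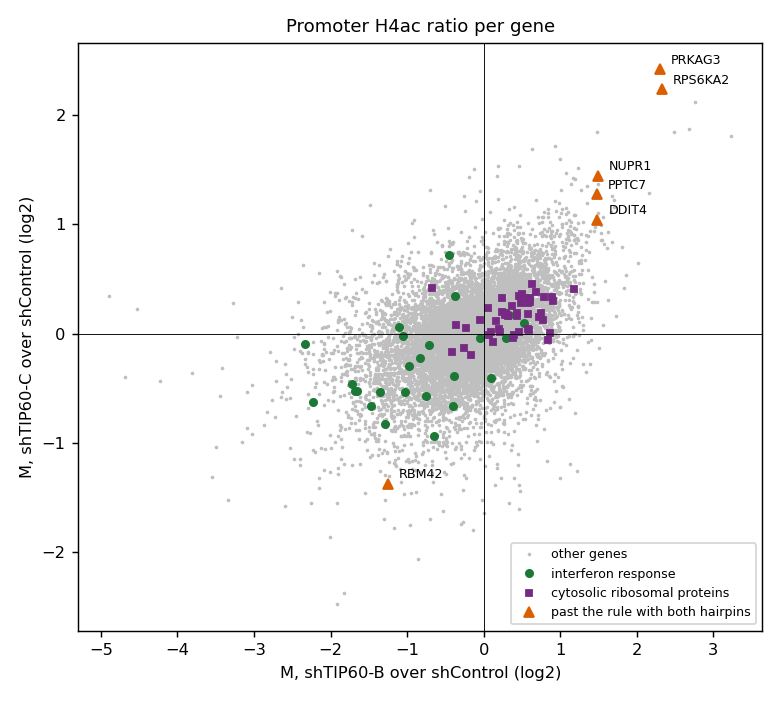
Promoter H4ac ratio (M, log2 of knockdown over control reads) of 11085 genes with shTIP60-B (horizontal axis) and shTIP60-C (vertical axis); each point is a gene, with the interferon response list, the cytosolic ribosomal protein list and the genes past the rule with both hairpins marked. RBM42 lies at the lower left and PRKAG3 at the upper right, at 2.30 and 2.42.

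Of 31 gene lists chosen before the data were examined, 4 lay beyond matched random lists with both hairpins. The interferon response list had a median of -0.83 (quartiles -1.36 and -0.39) with shTIP60-B and -0.39 (-0.54 and -0.04) with shTIP60-C over 25 measured genes, below all 10000 random lists each time. Of these genes, 8 fell and 17 did not pass with shTIP60-B, and none passed with shTIP60-C. Both medians of a list rest on the same control library, so its 2 percentiles are not independent. IRF9, a subunit of the interferon-activated ISGF3 complex, had M = -2.23 (-2.79 to -1.75) from 39 against 202 reads with shTIP60-B and -0.63 (-0.90 to -0.35) with shTIP60-C. The antiviral GTPase gene MX2 had M = -2.33 and -0.10, the transcription factor gene IRF7 -1.68 and -0.52, and IFI44L -1.66 and -0.53.

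Cytosolic ribosomal protein genes had a median of 0.44 (0.17 and 0.60) with shTIP60-B and 0.16 (0.02 and 0.29) with shTIP60-C over 46 genes, above all random lists each time. RPS24 rose with shTIP60-B, M = 1.18 (0.89 to 1.48), and the other 45 did not pass. RPS24 lies on chromosome 10, which was high as a whole, and centred in 10 Mb windows its M was 0.84, which ends its call. The list kept medians of 0.41 and 0.16 when centred. RPL14, RPLP1 and RPL11 had M = 0.90, 0.89 and 0.79 with shTIP60-B, and 0.29, 0.33 and 0.33 with shTIP60-C. The MYC family and core target list, made of ribosome biogenesis and growth genes, had medians of 0.23 and 0.17 over 24 genes, at the percentiles 99.4 and 99.7, with no member past the rule. NCL, the nucleolin gene, had M = 0.68 (0.49 to 0.87) and 0.52 (0.36 to 0.68), DDX21 0.84 and 0.26, EIF4G1 on chromosome 3 0.70 and 0.15 (0.16 with shTIP60-B when centred), and the spermidine synthase gene SRM 0.49 and 0.75. With ratios centred in 10 Mb windows, the percentile with shTIP60-C was 98.4, which ends the call for this list.

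Replication-dependent histone genes had medians of -0.66 and -0.22 over 21 genes, at the percentiles 0 and 0.46. HIST2H4A and HIST2H2BE fell with shTIP60-B, M = -1.67 and -1.12, and had M = -0.14 and -0.14 with shTIP60-C. HIST1H2BG had M = -1.35 and -0.24, and HIST1H3H -0.94 and -0.75. Most of these genes sit in a cluster on chromosome 6, which had a median of -0.21 with shTIP60-B, and matched random lists do not copy such a cluster. HIST2H2BE, on chromosome 1, had a centred M of -0.51, which ends its call. Centred in 10 Mb windows, the list had medians of -0.23 and -0.02 at the percentiles 4.33 and 29.5, but 118 of the 313 regions in the window of the cluster with shTIP60-B were themselves nearest to histone genes. With window medians that leave such regions out, the list had medians of -0.32 and -0.07 at the percentiles 0.985 and 10.5, so its call ended through shTIP60-C.

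The other 27 lists did not pass with both hairpins. Immediate early genes, which respond within minutes to growth signals, had a median of -0.50 over 20 genes with shTIP60-B, at the percentile 0.32, and -0.02 with shTIP60-C, at the percentile 39.5. TIP60 complex genes had medians of -0.27 and 0.01 over 16 genes, and other lysine acetyltransferase genes -0.45 and -0.25 over 12, at the percentiles 4.49 and 1.01. EGFR signalling genes had 0.01 and -0.0005 over 29, p53 targets 0.05 and 0.17 over 23, and G2/M genes -0.09 and -0.04 over 29. DNA double-strand break repair genes had -0.23 and -0.13 over 22, at the percentiles 22.1 and 6.01. Lung lineage genes had -0.40 and 0.06 over 6.

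**Figure D3:**
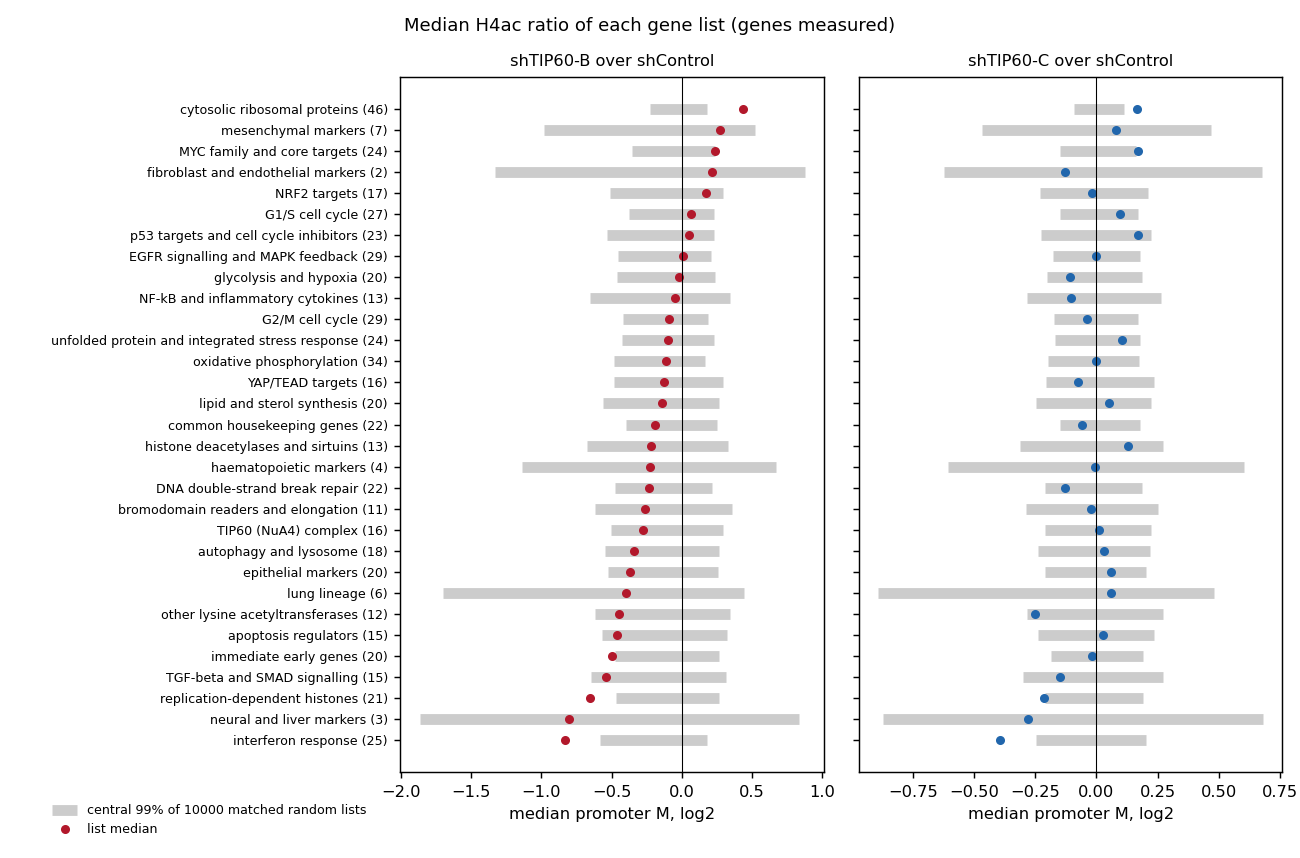
Median promoter M (log2, horizontal axis) of each of 31 gene lists with the number of measured genes, for shTIP60-B (left) and shTIP60-C (right, other scale); grey bars span the central 99% of 10000 random lists matched on signal. Interferon response genes (-0.83 and -0.39) and replication-dependent histones lie below the bars, and cytosolic ribosomal proteins (0.44 and 0.16) above them.

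Distal regions also passed with both hairpins. Among 37000 distal pairs of regions matched by at least 50% reciprocal overlap, 14 fell with both where independent lists would share 0.883, and 24 rose with both against 1.24. Pairs can repeat a region, and these lie at 11 and 20 distinct loci. Without the knockdown copies 10 and 13 pairs were left, and part of the excess may come from the shared control. The lowest lay 31570 bp from the LINC01252 start site (chromosome 12, 11732007 to 11733061, intergenic), with M = -3.38 (-5.29 to -2.31) and -1.91 (-2.63 to -1.26). The next were in intron 1 of PCSK5 (chromosome 9, 78518334 to 78519623), with M = -2.93 and -1.83, and near LINC00309 (chromosome 2, 64438433 to 64439870), with M = -2.21 and -1.50. By the smaller of its 2 ratios, the highest lay near TMEM106B (chromosome 7, 12209866 to 12210852, intergenic), with M = 2.83 (1.90 to 4.25) and 2.12 (1.22 to 3.54). Regions whose nearest start sites were those of LDLRAD2 (chromosome 1, 22182448 to 22183184, intronic) and SH2D6 (chromosome 2, 85672613 to 85674013, intergenic) had M = 2.06 and 1.93 with shTIP60-B and 1.96 and 2.24 with shTIP60-C.

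Across 58614 matched pairs of regions, which are not independent replicates, M of the hairpins correlated with Pearson r = 0.478 and Spearman rho = 0.463. Unchanged libraries sharing the control gave a simulated r of 0.541 and rho of 0.506 from counting error alone. The covariance was 0.178 against 0.0453 in the simulation, a difference of 0.133.

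A stretch beside the X centromere was singled out after its values were seen. Between 58004033 and 58293899 on chromosome X, 30 control peaks, of which 25 overlap satellite repeats, held 7578 control reads and 241 with shTIP60-B. That is 4.07% (3.57 to 4.63) of the control reads scaled by reads in control peaks, and 20 of the peaks fell. With shTIP60-C the peaks held 14066 reads, 100.1% (97.3 to 103), and none passed.

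**Figure D4:**
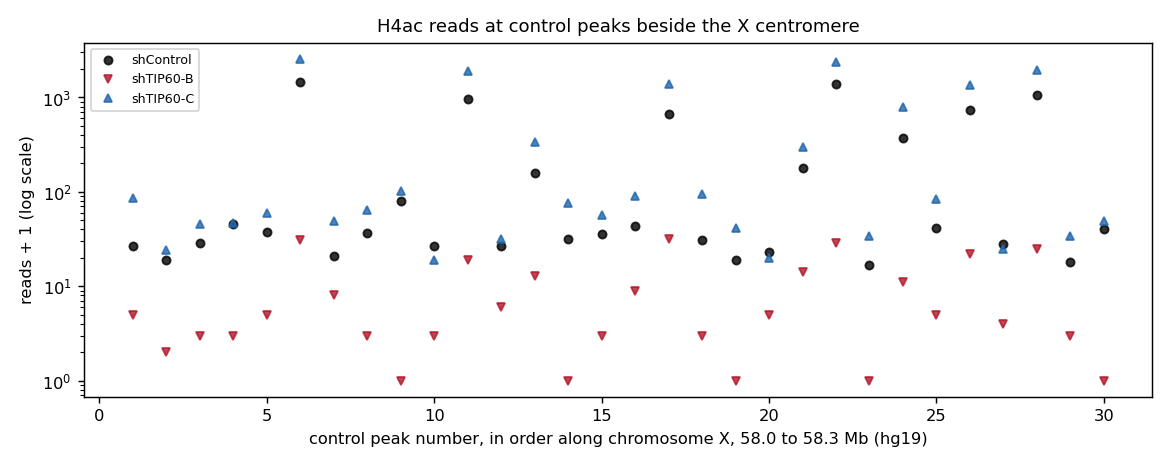
Reads plus 1 (log scale, vertical axis) at each of 30 control peaks beside the centromere of chromosome X, in order of position (horizontal axis), in the shControl, shTIP60-B and shTIP60-C H4ac libraries, not scaled for depth; each point is a peak. The shTIP60-B points lie below the control points, with 241 against 7578 reads in all, and the shTIP60-C library held 14066.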

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

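For chromosome-wide shifts, the tests of copy number, rescaling, an effect on whole chromosomes and an effect on chromosomes 16 and 20 were chosen after the result was seen, the last because the test over all chromosomes had left the question open; for the interferon promoters, so was that of the control library for shTIP60-C, split from a single test of that library.

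A first criterion, a low percentile with 1 hairpin and a high one with the other, picked out no list and was replaced after that was seen. Gene lists were then set apart when the median difference between the hairpins, from ratios centred in windows, lay beyond 99% of matched random lists in either direction. Interferon response genes differed by -0.58 between shTIP60-B and shTIP60-C, and immediate early genes by -0.43. Cytosolic ribosomal protein genes differed by 0.25, glycolysis and hypoxia genes by 0.24, and MYC family and core targets by 0.20. Chromosome 14 had medians of opposite sign, 0.084 with shTIP60-B and -0.059 with shTIP60-C, and that difference was not tested.

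The first pattern is the chromosome-wide shift with shTIP60-B. Counting noise is argued against: the SD of chromosome medians was 0.218 and the highest of 1000 shuffles 0.0291. Rescaling is argued against as well, since chromosome 20 lay -0.58 from the median of all regions with scaling by the table totals. Chromosomes 16 and 20 had a median of -0.018 (-0.03 to -0.0044) with shTIP60-C where a shared effect of TIP60 loss would give -0.13. That value assumes that chromosomes follow the slope between hairpins over regions, with the simulated covariance of the shared control taken off. Over 23 chromosomes, these included, the slope was 0.0858 (-0.0061 to 0.264), against 0.294 for locally centred promoter ratios. The interval lies below that value but did not meet the bound set for arguing against the effect. Over all chromosomes the effect thus stays open. A copy number difference between the lines may account for the shifts but stays open: promoter medians followed distal medians with a slope of 0.906 (0.801 to 0.992), which any cause acting on whole chromosomes would give, and the input libraries were not used here.

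The second pattern is the lower acetylation of interferon promoters. Chromosome-wide shifts are argued against: with centred ratios the list with shTIP60-B had a median of -0.91 at the percentile 0. Counting noise of the shared control is too small, since the median with shTIP60-C was -0.39 and the lowest of 1000 simulated was -0.145. Another deviation of the single control library would give both hairpins the same ratio, yet their difference lay at the percentile 0. Such a deviation is thus not the whole cause with shTIP60-B. Other differences of the 1 shTIP60-B culture would give this result too and cannot be told apart from an effect of TIP60 loss. For shTIP60-C the list lay at the percentile 0. An effect of TIP60 loss, other differences of the 1 shTIP60-C culture and a deviation of the 1 control library cannot be told apart there.

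The third pattern is the larger number of calls with shTIP60-B. After window centring 2449 regions passed with shTIP60-B and 176 with shTIP60-C, a ratio of 13.9, which argues against chromosome-wide shifts as the whole cause. Lower depth of shTIP60-B is argued against, since shTIP60-C thinned to 43.1% of its reads gave 217 to 255 regions in 20 thinnings by an exact binomial rule, against 2850 for shTIP60-B; the highest of 20 replaced a single thinning after that had been seen, with the bound of 0.1 of the shTIP60-B count left as it was. Rescaling of the deposited ratio is argued against as the whole cause by a ratio of 6.18 with total-scaled ratios and that rule. With the deposited values 3262 and 179 regions passed. Scaling by the table totals alone left 3019 and 175, and an exact binomial p alone gave 3015 and 469. The smaller ratio thus came with the exact binomial p, not with the scaling. A stronger knockdown and other differences between the cultures stay open and were not tested.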

How the results depend on the processing

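Scaling by the table totals or to the median of shared regions left all 6 counts within 1.5 times. With a fold of 1.5, 2362 regions rose with shTIP60-B, 146 fell and 316 rose with shTIP60-C, and 6 genes fell and 19 rose with both. With a fold of 3 the counts were 895 and 447, 7 and 63, and 0 and 2. A deposited p of 0.01 gave 5373 and 3282, 810 and 1152, and 20 and 33; a p of 1e-10 gave 652 and 427, 4 and 13, and 0 and 0. These follow from the thresholds. An exact binomial p gave 158 and 311 regions with shTIP60-C. With it 1 gene fell with both, ZNF362 (named after its values were seen) in place of RBM42. With the mean ratio over promoter regions 4 genes rose with both, without DDIT4. Of the choices made after seeing the data, dropping knockdown copies left 722 regions that rose with shTIP60-B and 95 with shTIP60-C. Leaving out the 9 shifted chromosomes left 719 and 628 regions, 16 and 64, and 1 gene that rose with both, PRKAG3, as fewer regions were counted. Without the 25% of regions lowest in signal 3 genes rose with both, DDIT4, NUPR1 and PPTC7. The shTIP60-B median of promoters was then -0.10 and that of distal regions 0.043, and the shTIP60-C distal median was -0.0011. With scaling by the table totals these were -0.053, 0.051 and -0.025. The sign of the shTIP60-B distal median thus turned with both, and the cause was not tested. The correlation was 0.468 for any overlap, 0.444 for identical coordinates, 0.454 without the lowest 25%, 0.461 for promoters, 0.468 with total scaling and 0.487 with window centring. Window centring left 2 of the 4 lists called; with histone regions left out of the window medians, the histone list kept its side with shTIP60-B (-0.32) but not with shTIP60-C (-0.071). Of 100 values of named genes, 97 kept their side of the rule with it; GPR146, RPS24 and HIST2H2BE did not, and the other scalings changed none. No paired analysis was possible because each group has 1 library. Depth limits the lowest ratios, many of which rest on under 10 reads.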

Other observations

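The ATF4 test was chosen after DDIT4, CHAC1, PSAT1, PHGDH, MTHFD2 and NUPR1 had been seen, and its list was put together then, before the values of its own members were looked at; the genes and regions described in the other paragraphs were also chosen after their values were seen.

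The list of unfolded protein and integrated stress response genes was not shifted, with medians of -0.10 and 0.10 at the percentiles 46.95 and 92.6, but some of its amino acid genes had higher ratios with both hairpins. In this list, DDIT4, PSAT1 and CHAC1 rose with shTIP60-B, M = 1.49, 1.18 and 1.12, and had M = 1.04, 0.74 and 0.76 with shTIP60-C, where DDIT4 rose. PSAT1 and PHGDH belong to serine synthesis and MTHFD2 to mitochondrial folate metabolism. PHGDH had M = 0.78 and 0.74, MTHFD2 0.63 and 0.72, ASNS, the asparagine synthetase gene, 0.32 and 0.50, and ATF4 itself 0.33 and 0.40. Chaperone and degradation genes of the same list were mixed, with -0.84 and -0.25 for DNAJB9, -0.14 and 0.26 for HSPA5, and 0.30 and 0.29 for HERPUD1. Other stress genes of this list that ATF4 is known to activate did not move alike. TRIB3, on chromosome 20 with its low median, had M = -0.66 and 0.62, and 0.08 and 0.59 when centred in 10 Mb windows. SESN2 had M = -0.61 and -0.41, DDIT3 -0.25 and 0.08, and SLC7A11 0.58 and -0.23.

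A candidate explanation is an ATF4 response to amino acid limitation with both hairpins. It was tested on 25 further known targets of ATF4 that had not been looked at, of which 21 were measured. Their medians were 0.38 (quartiles 0.23 and 0.56) with shTIP60-B and 0.26 (0.17 and 0.39) with shTIP60-C, at the percentiles 99.98 and 100 of matched random lists. Of the 21 genes, 0 passed the rule. Above 0 with both hairpins were 18 of the 21. SHMT2 had M = 0.49 (0.11 to 0.88) and 0.77 (0.48 to 1.09), STC2 0.59 and 0.48, and SLC3A2 0.64 and 0.33. The exceptions NARS, EPRS and MARS had M = -0.51, -0.25 and -0.13 with shTIP60-B, and 0.26, 0.16 and 0.17 with shTIP60-C. SESN2, with a negative M with both hairpins, and SLC7A11, with a negative one with shTIP60-C, are not in this list and did not share the higher ratios. The deposited p was 0.16 and 0.31 for SESN2 and 0.26 for SLC7A11 with shTIP60-C. These values thus do not decide for or against a uniform response. Ribosomal protein promoters also lay higher with both hairpins, so high percentiles are not particular to ATF4 targets and do not single out an ATF4 response. The control library is shared, so a lower state of this response in that 1 culture would look the same.

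In 0.5 Mb windows with at least 5 regions, 7 of 2829 had a median M of -2 or lower with shTIP60-B and 0 of 2826 with shTIP60-C. They include chromosome 16 near IRX5 (54667833 to 54971230, -2.33) and chromosome 9 at PCSK5 (78518334 to 78995371, -2.74). On chromosome 8, 9 control peaks between 128217273 and 129224316 held 1.96% of all control reads in control peaks. They held 2.35% with shTIP60-B and 2.28% with shTIP60-C, with a median M of 1.01 and 0.52. Together they held 120.4% and 116.6% of the control reads scaled by reads in control peaks, a smaller rise than the medians of single peaks.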
